A study of Andrias davidianus with 4 samples.

How the data were processed

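RNA was measured in the skin of the Chinese giant salamander, Andrias davidianus, a large aquatic amphibian. The series holds 4 libraries, 2 from wild type skin and 2 from albino skin, grouped by the titles and the genotype given in the labels. Per the labels' protocols, ribosomal RNA was removed from total RNA with a Ribo-Zero kit and libraries were made with a directional Illumina kit, which keeps the strand of the transcript. Trimmomatic, a read trimmer, is named in the submitters' processing notes without a version. The assembler, the aligner, the counting program and the genome build are not given in the sources used here.

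Each library had its own deposited table, and replicates were not pooled. Per the file headers, each table lists unigenes, which are assembled transcript sequences, with a length, a unique count and an FPKM value. The 4 tables list the same 110708 unigenes with the same lengths, from 301 to 34658 bases with a median of 534. The deposited unique counts are whole numbers of reads and are not normalized. Totals were 16854176 and 17256053 unique counts in the wild type libraries and 17361979 and 17547197 in the albino libraries. The FPKM values were computed by the authors per kilobase and scaled to the fragments of the library, per the file headers' unit. Whether the listed length was the one used is not given in the sources used here. FPKM was above 0 for 16847 to 17132 unigenes per library that had 0 unique counts, and never 0 where a unique count was present. The deposited FPKM therefore covers reads beyond the unique counts, and how such reads were divided is not given in the sources used here.

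The files do not pair unigenes with gene names or genome positions, and no genome was used. The 24 gene lists for pigment cells, skin cell types and general pathways, which were fixed before the data were examined, could therefore not be applied, and no list result is reported. Changes are described for unigenes as classes, and 4 unigenes are named by identifier.

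The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the unique counts of all 4 libraries, with TMM normalization, group as the only factor and 2 residual degrees of freedom. Unigenes were kept by edgeR's expression filter with its default minimum count of 10 and minimum total of 15, which left 37893 unigenes holding 99.0% of the unique counts. A unigene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are albino minus wild type on the log2 scale. Where both libraries of a group had 0 counts, the fold is given as a lower bound against a floor of 3 counts over that group. The floor in a single library is 3 counts, or 0.158 to 0.186 CPM, which are counts scaled to the TMM-adjusted library size. Such floors cover counting error only.

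The named unigenes follow a rule set beforehand for files without gene names. They are the 2 with the largest rise and the 2 with the largest fall among called unigenes whose mean lay at or above the median and whose groups did not overlap. Groups of 2 do not overlap by chance in 33.3% of unchanged unigenes.

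The test was tried on simulated counts drawn from the real means and library sizes for 37893 unigenes, 200 of them changed. With the spread estimated for each unigene, 64 of 100 changes of 2 on the log2 scale and 9 of 100 changes of 1 were called, with 17 unchanged unigenes among 90 calls. That false share of 18.9% exceeded the nominal level. With the spread taken from the trend over abundance, 77 of 100 and 23 of 100 were called, with 3 unchanged unigenes among 103 calls. The simulated share of changed unigenes was far below the 33.1% called in the data. Both the rate of calls and the false share depend on that share. The simulation also gave both groups the same spread for a unigene. In the data, the log2 difference between replicates had an SD of 0.25 in wild type and 0.55 in albino (6491 most abundant unigenes). For both reasons, the simulated values need not carry over to the real calls.

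Alternatives planned beforehand were leaving out each library, the replicate number as a block, DESeq2 size factors, no filter and a stricter filter on low counts, the DESeq2 Wald test (DESeq2 1.42.0), an adjusted p under 0.01 and a minimum log2 change of 1. A further planned setting kept only unigenes listed for all 4 libraries, which was every unigene. Added after seeing the data were limma (3.58.1) on log2(FPKM + 1) and on log2(FPKM + 0.1) for unigenes with an FPKM of at least 1 in 2 or more libraries, removal of the length trend, a crossed block, and other limits for unigenes read in one group only. FPKM per unique count was computed as FPKM times length in kilobases divided by the unique count, for unigenes with at least 50 counts in the library, and its log2 deviation was taken from the median of 30 length bins. Replicates are separate samples in the labels, which do not say whether they came from separate animals. The p-values then measure only the spread between these samples, which may be technical.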

Results

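Skin of wild type and albino Chinese giant salamanders was compared by RNA sequencing, with 2 libraries per group. The comparison asks which transcripts differ in level between pigmented and albino skin. Expression was read as unique counts on 110708 assembled unigenes, of which 79608 and 79867 had at least 1 count in the wild type libraries and 80724 and 84304 in the albino libraries. Depth was close across the libraries, from 16854176 to 17547197 unique counts.

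The replicates of a group resembled each other more than libraries of different groups. Across 37893 tested unigenes, which are not independent replicates, Pearson's r of log2 CPM was 0.977 between the wild type libraries and 0.957 between the albino libraries. Between the groups it ranged from 0.829 to 0.834. The libraries were not copies of one another. A chi-square statistic per unigene, which would be near 1 for sampling noise alone, was 5.08 for the wild type pair and 20.5 for the albino pair, and it lay between 73.2 and 76.6 for pairs across groups. Among the 6491 most abundant of the tested unigenes, the SD of the log2 difference between replicates was 0.25 in wild type and 0.55 in albino, and the albino gap was the larger one in 62.6% of them. With 1 such pair per group, this difference in spread was not tested.

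Between the albino and the wild type libraries, unigenes differed in both directions. Of the 37893 tested unigenes, 6170 were higher and 6361 lower in albino skin by edgeR's quasi-likelihood test at an adjusted p under 0.05, together 33.1% of those tested. The median log2 change was 1.38 among the unigenes that rose and -1.50 among those that fell, with a median standard error of 0.29 over all called unigenes (n = 2 per group). A change of at least 2-fold was found for 4145 of the higher and 4658 of the lower unigenes. A change of at least 8-fold was found for 852 and 1002, counting unigenes absent from one group at their lower bound. The median over all tested unigenes was 0.00 on the log2 scale. Leaving out either wild type library reduced the 12531 calls to 3690 without replicate 1 and 3934 without replicate 2, whereas 16604 and 15134 were called without albino replicate 1 and 2. DESeq2's Wald test called 7821 unigenes, 3933 higher and 3888 lower, all but 39 of them in edgeR's list with the same direction.

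**Figure D1:**
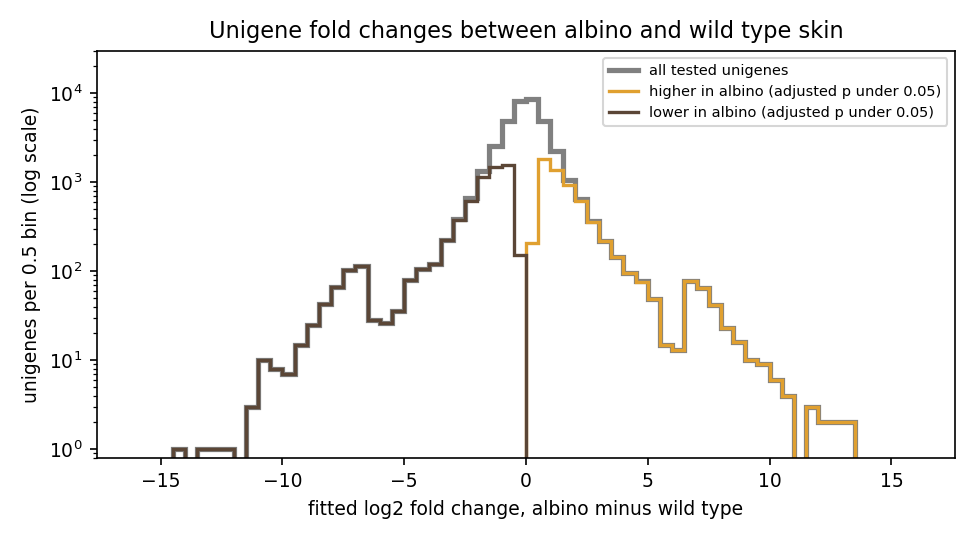
Number of unigenes (log scale) by fitted log2 fold change, albino minus wild type, in bins of 0.5, for all 37893 tested unigenes and for the 6170 higher and 6361 lower ones. Of the 703 called unigenes beyond 6 on either side, which form the outer humps, 633 had 0 counts in one group, and their fitted value depends on the prior count.

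The called unigenes were selected for differing, and their share of the reads is given as a description. The unigenes that rose made up 14.3% of the tested unique counts in both wild type libraries and 28.8% and 29.3% in the albino libraries. Those that fell made up 26.7% and 27.0% in wild type and 12.1% and 12.2% in albino. Unigenes that did not pass held 58.5% to 59.1% in each library.

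Of the 10 most abundant unigenes, 1 rose, 4 fell and 5 did not pass. The one that rose had a log2 change of 1.09 (SE 0.28, edgeR adjusted p = 0.0253), and the largest fall was -1.26 (SE 0.30, edgeR adjusted p = 0.0213). These 10 held 19.2% and 19.1% of unique counts in wild type and 18.8% and 14.8% in albino. Of the 100 most abundant, 17 rose, 17 fell and 66 did not pass, with the largest rise at 1.65 (SE 0.17, edgeR adjusted p = 0.00159) and the largest fall at -4.46 (SE 0.21, edgeR adjusted p = 0.000171). Of the 1000 most abundant, 217 rose, 202 fell and 581 did not pass.

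The 4 named unigenes, with the largest fitted changes, were present in one group and without unique counts in the other. UniGene_159430, 3831 bases long, had 1357 and 1096 unique counts in the albino libraries and 0 in both wild type libraries. Its mean was 70.7 ± 18.4 CPM (SD, n = 2) in albino, at least 773-fold higher than in wild type (edgeR adjusted p = 0.000227). UniGene_3384, 830 bases long, had 921 and 1210 counts in albino and 0 in wild type, at least 672-fold higher (60.3 ± 4.87 CPM, SD, n = 2, edgeR adjusted p = 0.000158). In the other direction, UniGene_58268, 479 bases long, had 2173 and 2126 counts in wild type and 0 in albino. That is at least 1516-fold lower in albino, from 129 ± 7.26 CPM in wild type (SD, n = 2, edgeR adjusted p = 0.000126). UniGene_111137, 449 bases long, had 1382 and 1308 counts in wild type and 0 in albino, at least 948-fold lower from 81.0 ± 6.44 CPM (SD, n = 2, edgeR adjusted p = 0.000158). Each of the 4 was listed with a minute but nonzero FPKM in at least 1 library of the group without unique counts, for example 1.95e-23 for UniGene_159430 in wild type replicate 1. FPKM covers reads beyond the unique counts, so the levels of these unigenes are uncertain where they share reads with another. The files name no gene for them.

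**Figure D2:**
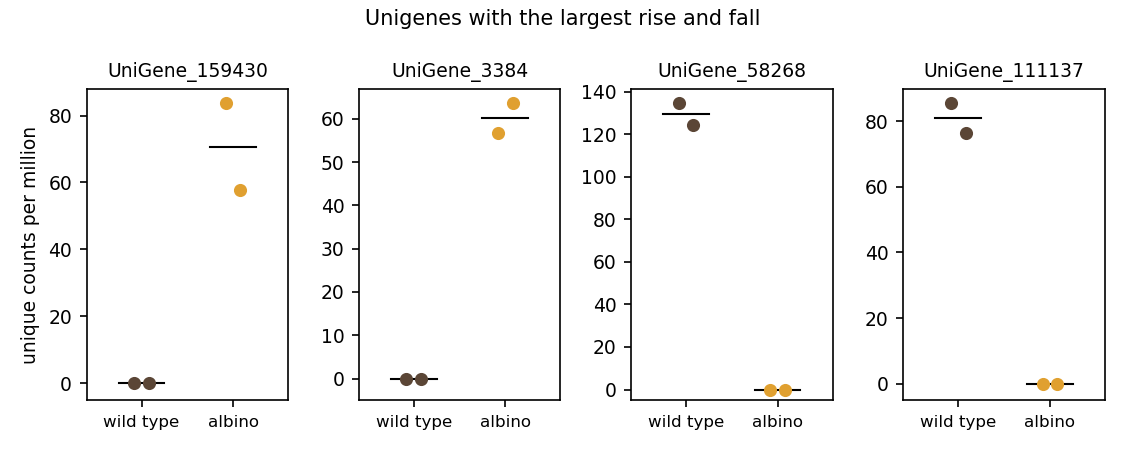
CPM (counts scaled to library size, linear axes, one scale per panel) of the 4 named unigenes in each library, with points for single libraries and lines for group means. Both libraries of one group lie at 0 in each panel, and those of the other lie between 56.8 and 134.

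Unique counts in one group only were found beyond these 4. With at least 10 unique counts in both libraries of one group and 0 in both of the other, 286 unigenes were read in albino only and 387 in wild type only. Their median lengths were 812.5 and 667 bases, and their median levels where present were 19.5 and 20 counts. In the empty group, FPKM was listed at 0 in both libraries for 194 of the 286 and 293 of the 387. It was under 5% of the other group's mean for 269 and 379, and the remaining 17 and 8 had more. FPKM in libraries without unique counts reached 2970 among the 286 and 220 among the 387. The 17 and 8 were without unique counts in one group but not without FPKM. Under the same limits, neither of the other 2 ways to split the 4 libraries 2 against 2 gave any such unigene. With 1 library left out, the count of 286 moved by more than 1.5 times without wild type replicate 1 (430) and without albino replicate 1 (735). That of 387 did so without albino replicate 2 (610). Both counts rose whichever library was left out, as fewer libraries had to meet the limits. That does not account for 735 in albino only without albino replicate 1 against 410 without albino replicate 2. Albino replicate 2 had fewer unigenes at 0 counts (26404) than albino replicate 1 (29984). At a minimum of 50 counts, 40 were read in albino only and 50 in wild type only. A unigene at 0 in a library can have a level of up to 0.186 CPM in unique counts at this depth. This floor does not bound reads beyond the unique counts, which FPKM covers.

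The balance of higher and lower unigenes was tabulated by length, as a description across unigenes, which are not independent. In the shortest sixth of tested unigenes, 301 to 592 bases long, the median log2 change was -0.23, with 991 higher and 1485 lower. In the longest, 2655 to 34658 bases, it was 0.08, with 1227 higher and 901 lower.

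The authors' FPKM gave the same direction as the unique counts for 12343 of the 12531 called unigenes (98.5%). Limma on log2(FPKM + 1) called 56.2% of them in the same direction, and 46.9% with a pseudocount of 0.1. It changed the test and the filter (54129 unigenes tested) as well as the measure. DESeq2 on the unique counts shared 62.1% of the calls, so the shortfall cannot be assigned to FPKM. Limma called 7764 unigenes higher and 5938 lower, and 6471 and 4653 with a pseudocount of 0.1. The FPKM values summed to 790950 and 782380 in the wild type libraries and to 848370 and 854350 in the albino libraries. The excess of higher calls was not separated from this offset. Among the called unigenes without the same direction by FPKM, 174 were lower by counts and higher by FPKM in albino, and 12 were higher by counts and lower by FPKM. FPKM per unique count was also spread differently in the groups. It lay more than 0.5 below its length trend on the log2 scale for 10.04% and 9.28% of unigenes in the wild type libraries, against 0.446% and 0.412% in the albino libraries. The labels give no batch, so no value within a batch and no fit with a batch term could be had. A difference in preparation or quantification that ran along the groups could therefore not be told apart from genotype. This holds for the calls by unique counts as well.

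**Figure D3:**
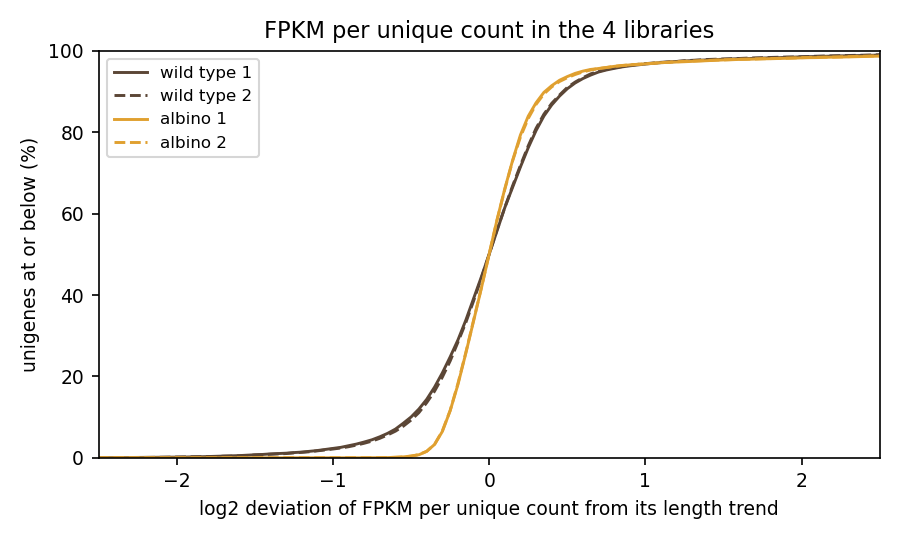
Cumulative share of unigenes (%) by the log2 deviation of FPKM per unique count from its length trend, one line per library, for unigenes with at least 50 unique counts. The wild type lines lie above the albino lines at deviations under 0, with 10.04% and 9.28% of unigenes below -0.5 against 0.446% and 0.412%.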

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

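All tests in this part were chosen after the data were seen. The groups of 2 are too small for a search for single outlying libraries.

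The authors' FPKM differed between the groups in unigenes without unique counts, which the count test could not see. Of 14708 unigenes without a unique count in any library, 826 had an FPKM of at least 1 in both albino libraries and at least 2-fold above both wild type libraries, and 451 showed the reverse. The other splits of the 4 libraries, which set a library of each group on both sides, gave 24 to 40. A unigene separated by group cannot also pass in those splits, so 24 to 40 is not a chance rate for the 826 and 451. These unigenes rest on FPKM alone. Where at least 50 unique counts were present, FPKM per unique count was spread differently in the groups. It lay more than 0.5 below its length trend for 10.04% and 9.28% of unigenes in wild type, against 0.446% and 0.412% in albino. Whether the FPKM calculation weighted unigenes without unique counts differently in the groups stays open.

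Among unigenes called lower in albino by unique counts, 174 were higher by FPKM, against 12 with the opposite conflict. Of these 174, 111 had at least 50 counts in every library. For the 111, shared reads that raised the albino FPKM above that of other unigenes are argued against. Their FPKM per unique count in albino deviated by a median of -0.045 (log2) from the median of unigenes of like length, with an interquartile range from -0.25 to 0.20. The rest of the 174, with fewer unique counts, were not covered. In wild type the same unigenes lay at -1.11 (log2), with an interquartile range from -1.50 to -0.68. A lower ratio in wild type than in albino is fixed by how the 174 were chosen, so this value does not test whether the FPKM calculation weighted them differently in the groups, which stays open, as do shared reads in other unigenes, which raise the median they are compared with. No biological explanation was tested, and the calculation behind the FPKM is not given in the sources used here.

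The 673 unigenes read in one group only are a further pattern. Chance absence at low counts is argued against for unigenes of equal level in the groups, since the other splits of the libraries gave at most 0. Those splits set a library of each group on both sides. They therefore cannot show whether unigenes lower in one group, but not silent there, fell to 0 counts by chance. Reads diverted to a near-identical unigene stay open: 487 were listed at exactly FPKM 0 in both empty libraries and 186, the 4 named ones included, were not, but FPKM values above 0 reach down to 3.11e-42 in the files, so that a listed 0 does not show that no read fell there. Sequence variants that make animals of one group map to another assembled copy cannot be told apart from transcripts that are switched off: of the unigenes with a mean of at least 100 counts in one group, 51 had 0 counts in the other, 25 had 1 to 3 and 38 had 4 to 10, in both directions, and no sequences were used. The difference between albino and wild type animals stays open as a biological explanation.

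The length trend is the third pattern. A difference in fragment length between the groups' libraries is a candidate explanation: FPKM per unique count on unigenes of up to 600 bases relative to those over 2000 bases was 1.66 and 1.62 in albino and 1.48 and 1.51 in wild type, so that the lowest albino value lay 0.107 above the highest wild type value. With 2 libraries per group, such a separation arises by chance in 33.3% of cases in either direction. The trend as the source of the calls is argued against, since 93.4% of the calls kept their direction and threshold once it was removed, when the median of the shortest sixth moved from -0.23 to -0.01. A real difference in transcripts of different length was not tested.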

How the results depend on the processing

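All settings below that concern FPKM, the length trend, the crossed block or the limits for unigenes read in one group only were chosen after seeing the data. No setting reversed a call of edgeR's count test except limma on FPKM, where 35 (pseudocount 1) and 31 (pseudocount 0.1) unigenes passed in the opposite direction. The 12531 calls moved by more than 1.5 times under 3 settings apart from left-out libraries: the stricter filter gave 8069 (4022 and 4047) from 27795 tested unigenes, DESeq2 7821 (3933 and 3888), and an adjusted p under 0.01 gave 5177 (2497 and 2680). Leaving out 1 library gave 3690 to 16604 calls, 1728 to 8183 higher and 1962 to 8421 lower. The low end came from leaving out a wild type library, which leaves the spread to the albino pair. With 1 library in an arm, it is assumed to vary like the other group. The replicate block gave 9022 calls (4463 and 4559). Same-numbered libraries did not deviate alike, as the correlation of their deviations across unigenes was -0.12, and crossing the numbers gave 13420 calls. With 1 pair per group, this does not settle whether the samples were paired. Size factors, no filter, a minimum change of 1 and removal of the length trend kept each count within 1.5 times. So did limma on FPKM, but with 7764 higher and 5938 lower (6471 and 4653 at pseudocount 0.1). It shared 56.2% and 46.9% of the 12531 calls, against 62.1% for DESeq2 on the unique counts. The 4 named unigenes kept their direction in all 56 repeats, which reuse the data they were chosen from. Unigenes read in albino only numbered 40 at 50 counts and 410 to 735 with 1 library left out. They numbered 430 without wild type replicate 1 and 735 without albino replicate 1. Those in wild type only numbered 50 and 523 to 610 (the highest without albino replicate 2). Fewer libraries must then meet the limits, but the size of the rise also depended on which library was left out. Over unigenes at or above the median level, the correlation of replicates was 0.985 in wild type and 0.952 in albino, against 0.977 and 0.957. With 1 pair per group these have no spread. Gene list tests were not run, as no unigene carries a name. A pseudocount, planned for a main test on normalized values, was not run, and the prior count behind fitted folds was not varied. No unigene was missing from a table. Depth limits unigenes of few counts, and the 72815 untested ones hold 0.999% of the unique counts. Depth is not the only limit: 14708 unigenes had no unique count in any library, and 1405 of these had an FPKM of at least 1 in all 4.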

Other observations

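The test in this part was chosen after the result was seen. The other 2 splits of the 4 libraries gave 0 calls each by edgeR's quasi-likelihood test, the only tool run on them, with 25 and 146 unigenes at an unadjusted p under 0.05. The real split gave 12531 calls and 17166 unigenes at that unadjusted level. The other splits set a library of each group on both sides, so a difference between the groups widens their residual spread. Their 0 calls therefore do not measure how many calls chance alone would give. The 3 possible splits, of which 1 gave as many calls, are too few for a share under 0.05.

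Albino replicate 2 had its reads spread over more unigenes than the other libraries. Its own 10 most abundant unigenes held 15.5% of its unique counts, against 19.3% in albino replicate 1 and 19.5% and 19.6% in wild type. It had 26404 unigenes at 0 counts, against 29984 to 31100 in the others.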
